A study of Homo sapiens with 36 samples.

How the data were processed

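RNA from 36 libraries of MV-4-11B cells was prepared with a poly(A) selecting kit that does not keep strand and was sequenced in pairs on a HiSeq instrument, per the labels' protocols. Samples were grouped by the treatment and time their titles give, as 12 groups of 3 libraries: DMSO, BI00894999 at 1 nM or 35 nM, volasertib at 20 nM, and volasertib with either dose, at 4 h and 24 h. CASAVA 1.8.2, HTSeq 0.5.3p9, Cufflinks 2.0.2 and DESeq are named per the submitters' processing notes, which also list the builds hg19 and hs37d5 with no role or order. The aligner, the annotation version, the DESeq version and any filter are not given in the sources used here.

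The files analysed were 10 tables of the authors' own comparisons, each a treatment against DMSO at 1 time, with 62069 genes listed by identifier, symbol, biotype and position. The authors deposited for each group a signal, the mean of normalized counts over its libraries, per the file headers. The deposited fold change is the ratio of the treated mean to the DMSO mean, and the deposited log2 fold change is its logarithm. The deposited p-value and adjusted p-value are the authors' own, and the adjusted values equalled a Benjamini-Hochberg adjustment over the tested genes to within 4.2e-07. A further column of moderated log2 fold changes, whose making is not given in the sources used here, was not used. No column of a single library was used.

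The planned tests on counts per library could not be fitted to group means, so, as planned for this case, the authors' fold change and adjusted p were taken as deposited, with a threshold of 0.05 and a 2-fold change as a second criterion. No spread per group, no left-out library and no interaction term could be computed from these tables. The tables had been normalized separately: DMSO means of the same libraries differ between tables, so tests were made within a table only. Dose, combination, sum and time contrasts, 17 in all, were set out as differences of log2 fold changes, with the median of each list placed among 10000 random lists of equal size matched on level. Overlaps of calls were counted between times only, where the DMSO libraries differ, beside the overlap of independent lists.

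Before the data were examined, 20 gene lists were written from general knowledge: BET inhibitor response markers, P-TEFb and BET genes, MYC targets, MLL fusion targets, G2/M and mitosis genes, G1/S and DNA replication genes, histone genes, p53 targets, BCL2 family and IAP genes, myeloid differentiation genes, interferon-induced genes, NF-kB and inflammatory genes, immediate early genes, FLT3, STAT5 and ERK output genes, cholesterol synthesis genes, ATF4 and amino acid response genes, spindle checkpoint genes, ribosomal protein genes, mitochondrially encoded genes, and markers of other cell types. Each list was tested in each table with cameraPR of limma 3.58.1 (R 4.3.3), two-sided, on z scores signed by the fold change and made from the authors' p, with p listed as 0 set to 1e-300, a preset correlation of 0.01, and Benjamini-Hochberg adjustment over the 200 tests. An estimated correlation needs values per library, so a correlation of 0.05 was run in its place; 77 of the 200 tests were called and 50 with 0.05, and each call lost is given with its p. Z scores were also simulated for the genes of 1 nM BI00894999 against DMSO at 4 h (13800 genes, 20 lists), drawn independently for each gene. On these the test called 48 of 50 lists shifted by 4 units (96.0%) and 2 of 300 unshifted lists. Such scores hold no correlation between genes, so they cannot show how often lists of correlated genes are called wrongly.

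Genes named in the text follow a rule set before the data were examined. MYC, HEXIM1, BCL2, PLK1, CCNB1 and CDKN1A are always eligible. From each table come the 6 risen and 6 fallen genes with the largest log2 fold change whose higher mean reached 5 CPM, without clone names and pseudogenes. From each list come up to 4 members, the 2 risen and 2 fallen with the smallest adjusted p, and the BET markers. From each contrast across tables come the 5 highest and 5 lowest genes, or 3 and 3 for time. The rule also asked that treated and DMSO values not overlap, which could not be applied without values per library, and the threshold was taken from the deposited adjusted p. Some genes that the rule takes are not reported here.

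Alternatives tried were adjusted p under 0.01, a log2 fold change of at least 1, a stricter filter on level with p adjusted again, leaving out genes that share both means with another gene, the correlation of 0.05, and tests on ranks. Depth per library is unknown. Low means fall on steps that gave relative depths in 7 of 20 group columns, where the deepest library had 1.131 to 1.725 times the depth of the shallowest. Whole reads were not recovered. Intervals for genes with 1 exon came from 2000 bootstrap draws of genes. GENCODE release 29 was used only for the number of exons, the GC content and the length of genes matched by identifier, and no coordinate was taken from it. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.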

Results

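Transcript levels were measured by RNA sequencing in MV-4-11B, an acute myeloid leukaemia cell line that carries an MLL-AF4 fusion and an internal tandem duplication of the receptor kinase FLT3. The cells had been given BI00894999, an inhibitor of the BET bromodomain proteins that bind acetylated chromatin, or volasertib, an inhibitor of the polo-like kinases of mitosis, or both drugs together. The 36 libraries form 12 groups of 3: DMSO, BI00894999 at 1 nM, BI00894999 at 35 nM, volasertib at 20 nM, and volasertib with either dose of BI00894999, each at 4 h and at 24 h. The 10 deposited tables each set 1 treatment against the DMSO libraries of its time and list 62069 genes, of which 13286 to 14191 had been tested. Group means of normalized counts summed to between 15.8 M and 20.9 M per group. The tables hold means and no values per library, so the spread between libraries enters only through the authors' p-values, and no SD can be given. The labels do not say whether the 3 libraries of a group came from separate cultures, so these p-values may measure technical spread. The library kit does not keep strand, so genes with an antisense or overlapping partner are uncertain, and histone genes share sequence with close copies. The kit also selects poly(A) RNA, so changes of histone genes given below are those of transcripts with a poly(A) tail. Total histone transcripts were not measured.

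**Figure D1:**
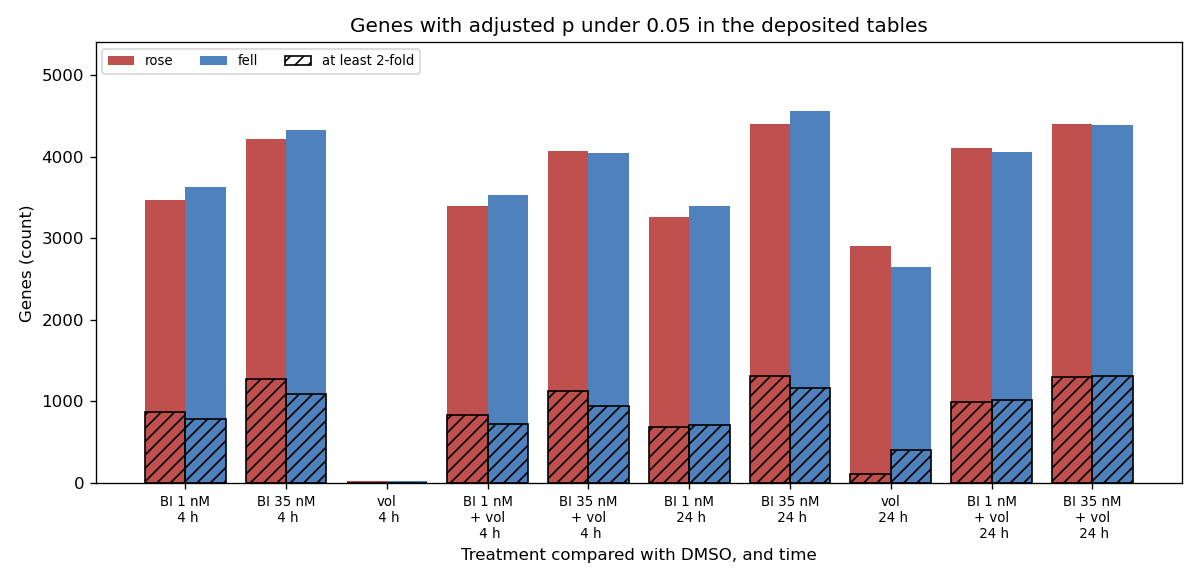
Bars give, for each treatment compared with DMSO at 4 h or 24 h (x axis), the number of genes (y axis) with an adjusted p under 0.05 that rose (red) or fell (blue), with the part changed at least 2-fold hatched. Volasertib at 4 h had 19 and 20 genes, and 35 nM BI00894999 with volasertib at 24 h had 4404 and 4383.

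The first question is what BI00894999 alone does at 4 h. At 35 nM, MYC, a transcription factor of growth, and BCL2, an inhibitor of apoptosis, fell, while HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose. Targets of MYC fell as a group, and histone genes rose as a group. The chemokine receptor gene CCR2 and the thrombin receptor gene F2RL3 were among the genes that fell most, and TEX14, a gene of germ cell bridges, was the named gene that rose most. The rise of TEX14 starts from few DMSO reads at 4 h, so its size is uncertain here and in the other comparisons of that time. F2RL3 lay near 5 CPM in DMSO at 4 h, so its treated means hold few reads. The size of its fall is uncertain too. In the authors' deposited table, MYC went from a mean of 11708 to 5663 normalized counts (log2 fold change -1.05, adjusted p = 4.69e-86). HEXIM1 went from 1098 to 6132 (log2 2.48, adjusted p = 3.56e-88) in the authors' deposited table, and BCL2 from 3002 to 1149 (log2 -1.39, adjusted p = 1.1e-99). CCR2 fell from 4104 to 103 in the authors' deposited table (log2 -5.31, adjusted p listed as 0). CDKN1A, an inhibitor of cyclin-dependent kinases, rose (log2 1.40, adjusted p = 3.13e-60), while PLK1 (log2 -0.36) and the mitotic cyclin gene CCNB1 (log2 -0.24) fell, per the authors' deposited table. Among genes that reached 5 CPM in 1 of the groups, leaving out clone names and pseudogenes here and in the other comparisons, the largest rises in the authors' deposited table were those of TEX14 (log2 8.81), EFR3B (6.24), BAIAP3 (6.11), MAFA (5.999), HIST1H3D (5.75) and NXN (5.65). The largest falls there were those of F2RL3 (log2 -5.41), CCR2, KANK1 (-4.80), HSH2D (-4.58), CXCR3 (-4.21) and NAV3 (-4.20), per the authors' deposited table. By that table's test, 8543 of 13967 tested genes passed an adjusted p of 0.05, 4215 higher and 4328 lower, of which 1275 and 1090 changed by at least 2-fold. The tables place MYC on chromosome 8 from 128747680 to 128753674, HEXIM1 on chromosome 17 from 43224684 to 43229468, BCL2 on chromosome 18 from 60790579 to 60987361 and CCR2 on chromosome 3 from 46395225 to 46402419, all annotated as protein coding, and the builds named in the submitters' processing notes are hg19 and hs37d5.

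Gene lists fixed beforehand moved as follows with 35 nM at 4 h. Among the MYC targets, 1 of 51 measured members rose, 46 fell and 4 did not pass, the same as adjusted over the list alone, with median log2 -0.73, adjusted p = 1.5e-19 for the list. Examples in the authors' deposited table are the nucleolar genes MYBBP1A (log2 -1.60) and MRTO4 (-1.36), against NPM1 (0.16), which rose. Among histone genes, 17 of 18 measured members rose and 1 did not pass, against 18 higher adjusted over the list alone (median log2 2.76, adjusted p = 4.2e-13). HIST1H2AC stood at log2 4.25 and HIST1H2BD at 3.74 in the authors' deposited table. Among immediate early genes, which respond first to growth signals, 15 of 21 measured members rose, 2 fell and 4 did not pass, the same as adjusted over the list alone (median log2 0.95, adjusted p = 0.00036). EGR1 rose (log2 1.79) and FOSL2 fell (-0.84) in the authors' deposited table. Among p53 targets, 18 of 25 measured members rose, 6 fell and 1 did not pass, the same as adjusted over the list alone (median log2 0.61, adjusted p = 0.00015). The stress sensor gene SESN2 stood at log2 1.61 and the nuclease gene AEN at -0.97 in the authors' deposited table. Among genes of P-TEFb and the BET proteins, 11 of 18 measured members rose, 5 fell and 2 did not pass, the same as adjusted over the list alone (median log2 0.27, adjusted p = 0.01, but adjusted p = 0.064 with a correlation of 0.05). The elongation factor gene ELL2 rose (log2 2.15) and LARP7, which holds P-TEFb in its inactive complex, fell (-0.77) in the authors' deposited table. Among genes of myeloid differentiation, 4 of 26 measured members rose, 12 fell and 10 did not pass, the same as adjusted over the list alone (median log2 -0.38, adjusted p = 0.032, but adjusted p = 0.16 with a correlation of 0.05), with the transcription factor gene IRF8 (log2 -1.500) and the receptor gene CSF1R (-1.53) among those that fell in the authors' deposited table. All 13 mitochondrially encoded genes rose (median log2 0.24, adjusted p = 0.0067, but adjusted p = 0.064 on ranks of the log2 fold change). Among ribosomal protein genes, 25 of 42 measured members rose and 17 did not pass, the same as adjusted over the list alone (median log2 0.19, adjusted p = 0.017, but adjusted p = 0.16 with a correlation of 0.05). Of these, 7 mitochondrial and 5 ribosomal genes share both of their group means with another gene, as several abundant genes of the table do.

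Several lists were not called with 35 nM at 4 h. Markers of BET inhibition moved both ways, and 6 of 10 measured members rose and 4 fell, the same as adjusted over the list alone (adjusted p = 0.99), with SERPINI1 at log2 4.92 and CD180 at -3.34 in the authors' deposited table. All 10 thus passed. The list test asks for a shared direction, so opposite moves cancel in it and its p does not speak against a response of these markers. Among the MLL fusion targets, 8 of 23 measured members rose, 12 fell and 3 did not pass, the same as adjusted over the list alone (adjusted p = 0.065), and SENP6 (log2 -2.44) fell while HOXA9 (0.97), a homeobox gene of leukaemic self-renewal, rose in the authors' deposited table. In the BCL2 family, 5 of 15 measured members rose, 6 fell and 4 did not pass, the same as adjusted over the list alone (adjusted p = 0.95), with MCL1 at log2 1.01 and BCL2L1 at -0.998 in the authors' deposited table, both inhibitors of apoptosis. The G1/S genes (adjusted p = 0.95), G2/M genes (0.16), spindle checkpoint genes (0.82), NF-kB genes (0.8) and interferon-induced genes (0.2) were not called. Of the markers of other cell types 4 were measured (adjusted p = 0.95), among them KRT18, an epithelial keratin gene, which fell (log2 -0.90) in the authors' deposited table.

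At 1 nM, BI00894999 lowered MYC and BCL2 and raised HEXIM1 at 4 h, CCR2 fell most among genes that reached 5 CPM, and histone genes rose while MYC targets fell. MYC in the authors' deposited table had a log2 fold change of -0.85 (adjusted p = 1.31e-46), BCL2 of -1.48, HEXIM1 of 1.85 and CDKN1A of 0.94. CCR2 fell from 3607 to 146 normalized counts (log2 -4.63) in the authors' deposited table, followed by SCIMP (-4.09), NAV3 (-4.06), NFE2 (-3.95), SH3TC1 (-3.85) and HSH2D (-3.85). EFR3B (log2 6.14), NXN (5.46), AP3B2 (4.94), CAPN5 (4.63), PTCHD2 (4.60) and the growth factor receptor gene FGFR3 (4.59) rose most among such genes in the authors' deposited table. Below that level, F2RL3 (log2 -5.04) fell and TEX14 (7.38) rose in the authors' deposited table. Among MYC targets, 44 of 51 measured members fell and 7 did not pass, against 47 lower adjusted over the list alone (median log2 -0.63, adjusted p = 5.4e-19). SLC19A1 stood at log2 -1.20 in the authors' deposited table. Among histone genes, 14 of 17 measured members rose and 3 did not pass, against 15 higher adjusted over the list alone (median log2 2.55, adjusted p = 4.9e-11). The immediate early list rose, where 17 of 22 measured members rose, 2 fell and 3 did not pass, the same as adjusted over the list alone (median log2 1.06, adjusted p = 3.7e-06), and so did the p53 list. Of its genes, 16 of 25 measured members rose, 4 fell and 5 did not pass, the same as adjusted over the list alone (median log2 0.38, adjusted p = 0.00079, but adjusted p = 0.051 on ranks of the log2 fold change). FOS rose (log2 1.22) and so did the cyclin gene CCNG1 (0.80) in the authors' deposited table. Among MLL fusion targets, 5 of 23 measured members rose, 12 fell and 6 did not pass, against 6 higher and 13 lower adjusted over the list alone (median log2 -0.25, adjusted p = 0.0066, but adjusted p = 0.064 with a correlation of 0.05). The P-TEFb list (median log2 0.23, adjusted p = 0.017, but adjusted p = 0.095 with a correlation of 0.05) rose and the myeloid list (median log2 -0.32, adjusted p = 0.014, but adjusted p = 0.1 with a correlation of 0.05) fell. By the authors' test, 7094 of 13817 tested genes passed an adjusted p of 0.05, 3464 higher and 3630 lower, of which 872 and 786 changed by at least 2-fold.

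Volasertib alone at 4 h moved few genes. EGR1 and FOS, immediate early transcription factor genes, rose, and AHR, the receptor for dioxins, fell. TOP2A, the topoisomerase of dividing cells, also fell, and the kinase gene VRK1 and FLT3 rose. EGR1 in the authors' deposited table went from 531 to 1127 normalized counts (log2 1.08, adjusted p = 3.77e-41) and FOS had a log2 of 0.62 (adjusted p = 3.67e-15). ADAMTS13 (log2 0.65), RFX8 (0.34), VRK1 (0.34) and ARHGAP15 (0.28) also rose in the authors' deposited table. Of genes that passed the test and reached 5 CPM, the lowest there were PAN3-AS1 (log2 -0.79), ARTN (-0.67), EPM2AIP1 (-0.54), SNHG10 (-0.51), AHR (-0.47) and KLHL9 (-0.40), per the authors' deposited table. TOP2A had a log2 of -0.26 (adjusted p = 5.33e-06) and FLT3 of 0.22 (adjusted p = 0.00523) in the authors' deposited table. MYC (log2 0.00, adjusted p = 1), PLK1 (0.15, adjusted p = 0.57) and CDKN1A (-0.05, adjusted p = 1) did not pass the test in the authors' deposited table. By that test 39 of 13485 genes passed, 19 higher and 20 lower, against 884 at an unadjusted p under 0.05. Among the immediate early genes, 3 of 20 measured members rose and 17 did not pass, against 7 higher and 2 lower adjusted over the list alone (median log2 0.02, adjusted p = 2e-07), though the list was not called on ranks of z (adjusted p = 0.59) or ranks of the log2 fold change (0.61). Small shared shifts were called upward for the MLL fusion targets (median log2 0.06, adjusted p = 0.0008, but adjusted p = 0.067 on ranks of the log2 fold change), where ZEB2 and FLT3 rose, and for ribosomal protein genes (median log2 0.05, adjusted p = 3.1e-05), of which 6 share both means with another gene. Spindle checkpoint genes were called upward (median log2 0.04, adjusted p = 0.0029, but adjusted p = 0.083 on ranks of the log2 fold change) with 2 members higher adjusted over the list alone. G1/S genes were called downward (median log2 -0.05, adjusted p = 0.0016, but adjusted p = 0.053 with a correlation of 0.05) with 2 members lower adjusted over the list alone.

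With both drugs for 4 h, MYC, BCL2 and CCR2 fell and HEXIM1 rose against DMSO at either dose of BI00894999, as with BI00894999 alone. INHBA, which encodes an activin subunit, was among the genes that fell most at either dose. With 1 nM the receptor gene GPR183 was also among those that fell most, and JUP, a gene of cell junctions, among those that rose most. In the authors' deposited tables MYC had a log2 of -0.93 with 1 nM and -0.997 with 35 nM, HEXIM1 of 1.77 and 2.26, BCL2 of -1.10 and -1.04, and CDKN1A of 1.02 and 1.44. With 1 nM the extremes of the authors' deposited table among genes that reached 5 CPM were EFR3B (log2 5.84), NXN (5.35), AP3B2 (4.77), CAPN5 (4.58), PTCHD2 (4.57) and JUP (4.48). At its other end stood KANK1 (-3.81), CCR2 (-3.59), SH3TC1 (-3.51), INHBA (-3.50), SCIMP (-3.25) and GPR183 (-3.14), while HSH2D (-4.32), F2RL3 (-4.22) and TEX14 (7.43) lay below that level, per the authors' deposited table. With 35 nM the extremes at that level were TEX14 (log2 8.57), EFR3B (6.28), NXN (5.96), MAFA (5.81), HIST1H3D (5.44) and AP3B2 (5.33) in the authors' deposited table. The lowest there were HSH2D (-4.63), INHBA (-3.84), CCR2 (-3.75), B3GNT7 (-3.71), NFE2 (-3.71) and F2RL3 (-3.65). By the authors' test with 1 nM, 6924 of 14191 tested genes passed an adjusted p of 0.05, 3392 higher and 3532 lower, of which 832 and 729 changed by at least 2-fold. With 35 nM, 8114 of 13958 tested genes passed an adjusted p of 0.05, 4064 higher and 4050 lower, of which 1132 and 944 changed by at least 2-fold.

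Among MYC targets in the combinations at 4 h, 45 of 51 measured members fell and 6 did not pass, against 46 lower adjusted over the list alone with 1 nM (median log2 -0.58, adjusted p = 1.5e-19). With 35 nM, 45 of 51 measured members fell and 6 did not pass, against 1 higher and 45 lower adjusted over the list alone (median log2 -0.71, adjusted p = 3.7e-18). NOP16, a gene of ribosome assembly, had a log2 of -1.09 with 1 nM in the authors' deposited table. Among histone genes, 13 of 18 measured members rose and 5 did not pass, against 14 higher adjusted over the list alone with 1 nM (median log2 1.72, adjusted p = 1.3e-06). With 35 nM, 17 of 18 measured members rose and 1 did not pass, the same as adjusted over the list alone (median log2 2.29, adjusted p = 8.7e-14). The immediate early list rose with 1 nM, where 16 of 23 measured members rose, 2 fell and 5 did not pass, the same as adjusted over the list alone (median log2 0.98, adjusted p = 1.4e-05). It also rose with 35 nM, where 15 of 21 measured members rose, 3 fell and 3 did not pass, the same as adjusted over the list alone (median log2 1.06, adjusted p = 5.1e-06). Among the p53 targets, 14 of 25 measured members rose, 4 fell and 7 did not pass, against 15 higher and 5 lower adjusted over the list alone with 1 nM (median log2 0.48, adjusted p = 0.00073, but adjusted p = 0.057 on ranks of the log2 fold change). With 35 nM, 18 of 25 measured members rose, 5 fell and 2 did not pass, the same as adjusted over the list alone (median log2 0.56, adjusted p = 3.7e-05). The P-TEFb list rose with 1 nM (median log2 0.23, adjusted p = 0.0033) and with 35 nM (median log2 0.28, adjusted p = 0.0057), though not on ranks of z (adjusted p = 0.15 and 0.13) or ranks of the log2 fold change (0.38 and 0.32). The myeloid list fell with 1 nM (median log2 -0.35, adjusted p = 0.012, but adjusted p = 0.1 with a correlation of 0.05). With 35 nM the G2/M list was called upward, where 21 of 42 measured members rose, 5 fell and 16 did not pass, the same as adjusted over the list alone (median log2 0.17, adjusted p = 0.032, but adjusted p = 0.22 with a correlation of 0.05). HMMR, a gene of the spindle, stood at log2 0.85 and the ubiquitin enzyme gene UBE2C at -0.43 in the authors' deposited table. Ribosomal protein genes (median log2 0.22, adjusted p = 0.0062, but adjusted p = 0.11 with a correlation of 0.05) and mitochondrially encoded genes (median log2 0.22, adjusted p = 0.033, but adjusted p = 0.11 with a correlation of 0.05) also rose as lists with 35 nM, of which 4 and 6 share both means with another gene.

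After 24 h of BI00894999 alone, IGLL1, a gene of the surrogate light chain, the proteoglycan gene CSPG4 and CCR2 were among the genes that fell most at both doses, and EFR3B rose most, among genes that reached 5 CPM. The myeloid differentiation list fell, with the lysozyme gene LYZ and the cathepsin gene CTSG among its fallen members and the integrin genes ITGAM and ITGAX among those that rose. The list of DNA replication genes fell with 35 nM. In the authors' deposited table for 35 nM, IGLL1 had a log2 of -8.53, CSPG4 of -6.69, the interleukin receptor gene IL2RA of -6.41, CCR2 of -6.37, CST7 of -6.28 and GGT5 of -5.91. EFR3B (log2 8.54), DHRS2 (6.15), CAPN5 (5.03), AP3B2 (4.92) and SSPO (4.85) were among those that rose most with 35 nM in the authors' deposited table. With 1 nM, IGLL1 went from 447 to 2.96 normalized counts (log2 -7.24) in the authors' deposited table, ahead of CSPG4 (-4.99), CXCR3 (-4.94), CCR2 (-4.87), IL7R (-4.81) and GGT5 (-4.74). EFR3B (log2 7.74), AP3B2 (4.39), NXN (4.35), CAPN5 (4.15), EGR1 (3.81) and JUP (3.56) rose most with 1 nM at that level in the authors' deposited table. MYC had a log2 of -0.61 with 1 nM and -0.78 with 35 nM in the authors' deposited tables, HEXIM1 of 1.16 and 1.40, BCL2 of -1.12 and -1.497, and CDKN1A of 1.08 and 1.85. By the authors' test with 1 nM, 6657 of 13565 tested genes passed an adjusted p of 0.05, 3257 higher and 3400 lower, of which 691 and 710 changed by at least 2-fold. With 35 nM, 8949 of 14105 tested genes passed an adjusted p of 0.05, 4395 higher and 4554 lower, of which 1307 and 1164 changed by at least 2-fold.

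Among MYC targets at 24 h of BI00894999, 44 of 51 measured members fell and 7 did not pass, against 45 lower adjusted over the list alone with 1 nM (median log2 -0.56, adjusted p = 2.2e-14). With 35 nM, 1 of 51 measured members rose, 47 fell and 3 did not pass, against 1 higher and 48 lower adjusted over the list alone (median log2 -0.69, adjusted p = 2.6e-16). PA2G4, a gene of cell proliferation, had a log2 of -1.07 and ODC1, the first enzyme of polyamine synthesis, of 0.30 with 35 nM in the authors' deposited table. Among genes of myeloid differentiation, 5 of 25 measured members rose, 13 fell and 7 did not pass, the same as adjusted over the list alone with 1 nM (median log2 -0.28, adjusted p = 5.8e-07). With 35 nM, 5 of 25 measured members rose, 16 fell and 4 did not pass, the same as adjusted over the list alone (median log2 -0.95, adjusted p = 2.7e-07). LYZ went from 67183 to 3162 normalized counts with 35 nM (log2 -4.41) in the authors' deposited table, CTSG had a log2 of -3.81, ITGAM of 2.30 and ITGAX of 1.62. With 1 nM the myeloid list was not called on ranks of z (adjusted p = 0.084) or ranks of the log2 fold change (0.11). Among G1/S and replication genes, 5 of 38 measured members rose, 22 fell and 11 did not pass, against 5 higher and 24 lower adjusted over the list alone with 1 nM (median log2 -0.20, adjusted p = 0.038, but adjusted p = 0.22 with a correlation of 0.05). With 35 nM, 4 of 38 measured members rose, 30 fell and 4 did not pass, the same as adjusted over the list alone (median log2 -0.44, adjusted p = 2.6e-06). The helicase subunit genes MCM5 (log2 -1.10) and MCM2 (-0.995) fell and TK1 (0.62), the thymidine kinase, rose with 35 nM in the authors' deposited table. The G2/M list rose with 35 nM, where 23 of 42 measured members rose, 5 fell and 14 did not pass, the same as adjusted over the list alone (median log2 0.17, adjusted p = 0.017, but adjusted p = 0.16 with a correlation of 0.05). CKAP2 stood at log2 1.08 in the authors' deposited table. The histone list rose with 1 nM, where 11 of 15 measured members rose and 4 did not pass, the same as adjusted over the list alone (median log2 1.40, adjusted p = 5.7e-05). It also rose with 35 nM, where 13 of 18 measured members rose and 5 did not pass, the same as adjusted over the list alone (median log2 2.09, adjusted p = 7.4e-06). The immediate early list rose with 1 nM, where 17 of 21 measured members rose, 2 fell and 2 did not pass, the same as adjusted over the list alone (median log2 0.96, adjusted p = 4.5e-11). It also rose with 35 nM, where 19 of 22 measured members rose, 2 fell and 1 did not pass, the same as adjusted over the list alone (median log2 1.34, adjusted p = 1.1e-10). The P-TEFb list rose with 1 nM (median log2 0.08, adjusted p = 0.048, but adjusted p = 0.17 with a correlation of 0.05) and with 35 nM (median log2 0.07, adjusted p = 0.033, but adjusted p = 0.14 with a correlation of 0.05). The p53 targets were not called with 1 nM (adjusted p = 0.27) or 35 nM (adjusted p = 0.081). The BET marker list had positive medians (0.81 and 1.47) while its test pointed down, without a call (adjusted p = 0.32 and 0.85). All of its measured members passed, 5 higher and 4 lower with 1 nM and 6 higher and 4 lower with 35 nM. Opposite moves cancel in the list test.

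Volasertib alone at 24 h raised CDKN1A and the mitotic genes CCNB1, PLK1 and HMMR. It lowered genes of DNA replication, among them CCNE2, the cyclin of S phase entry, and the repair gene UNG. EGR1, FOSB and FOS rose, and the homeobox genes HOXA9 and HOXA10 fell. Alongside, genes with 1 exon had a median log2 of -0.272 and antisense genes of -0.44, against 0.029 for genes with several exons, and the internal numbers of 2 of the 3 volasertib libraries lie outside the run of the others. CDKN1A in the authors' deposited table went from 507 to 1714 normalized counts (log2 1.76, adjusted p = 6.05e-130), CCNB1 had a log2 of 1.09 (adjusted p = 5.11e-109) and PLK1 of 0.72 (adjusted p = 4.29e-38). MYC (log2 -0.35) and HEXIM1 (-0.22) fell and BCL2 (0.31) rose, per the authors' deposited table. Among genes that reached 5 CPM, the largest rises in the authors' deposited table were those of EGR1 (log2 3.27), FOSB (2.86), NCF1 (2.62), FOS (2.36) and BCL3 (2.04). Below that level EGR3 (log2 4.93), EGR2 (4.797), NAV2 (3.25) and HMOX1 (2.89) rose in the authors' deposited table. ADAT3 (log2 -2.55), CCNE2 (-2.53), HNRNPU-AS1 (-2.45), TEX22 (-2.32), SNHG10 (-2.23) and FAM201A (-2.17) fell most at 5 CPM or above in the authors' deposited table. HNRNPU, for which HNRNPU-AS1 is named as antisense, was chosen after its values were seen and had a log2 of -0.24 (adjusted p = 0.0861) in the authors' deposited table. By the authors' test, 5546 of 13286 tested genes passed an adjusted p of 0.05, 2900 higher and 2646 lower, of which 107 and 399 changed by at least 2-fold. Among G1/S and replication genes, 1 of 38 measured members rose, 31 fell and 6 did not pass, against 1 higher and 34 lower adjusted over the list alone (median log2 -0.44, adjusted p = 4e-22). UNG stood at log2 -1.17 and PCNA, the sliding clamp, at -0.65 in the authors' deposited table. Among G2/M genes, 20 of 42 measured members rose, 13 fell and 9 did not pass, against 21 higher and 15 lower adjusted over the list alone (median log2 0.12, adjusted p = 0.045, but adjusted p = 0.25 with a correlation of 0.05), where HMMR rose (log2 1.20) and TOP2A (-1.31) and CDK1 (-1.22) fell in the authors' deposited table. Among p53 targets, 11 of 25 measured members rose, 1 fell and 13 did not pass, the same as adjusted over the list alone (median log2 0.21, adjusted p = 0.00012). BTG2 stood at log2 1.26 in the authors' deposited table. Among immediate early genes, 11 of 22 measured members rose, 4 fell and 7 did not pass, against 12 higher and 4 lower adjusted over the list alone (median log2 0.23, adjusted p = 0.00066). JUND stood at log2 -1.13 in the authors' deposited table. On ranks of z this list was not called (adjusted p = 0.069). Among MYC targets, 21 of 51 measured members rose, 6 fell and 24 did not pass, against 22 higher and 6 lower adjusted over the list alone (median log2 0.13, adjusted p = 0.048, but adjusted p = 0.28 with a correlation of 0.05). Among ribosomal protein genes, 20 of 42 measured members rose and 22 did not pass, against 21 higher adjusted over the list alone (median log2 0.14, adjusted p = 0.0057, but adjusted p = 0.1 with a correlation of 0.05). Of the latter, 2 share both means with another gene. HOXA9 (log2 -0.84) and HOXA10 (-0.85) fell in the authors' deposited table while the MLL fusion list was not called (adjusted p = 0.8). The spindle checkpoint list was not called (adjusted p = 0.57), with CDC20 at log2 0.98 and SPC24 at -1.04 in the authors' deposited table.

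With both drugs for 24 h, the early growth response genes EGR2 and EGR3 were among the genes that rose most. The list of NF-kB signalling and inflammation rose, with IER3, TNF and RELB among its risen members, and so did the complement gene C3. Mitotic genes rose as a group and genes of DNA replication fell as a group, and the receptor genes IL7R, CLEC12A and CCR2 were among those that fell most. Genes with 1 exon had a median log2 of -0.089 with 1 nM and -0.045 with 35 nM. Antisense genes had -0.229 and -0.19, against 0.015 and 0.006 for genes with several exons. Of the 3 libraries with 35 nM and volasertib, 1 has an internal number outside the run of the others. In the authors' deposited table for 1 nM with volasertib, EFR3B (log2 7.09), EGR2 (6.65), EGR3 (6.64), EGR1 (4.99) and CAPN5 (4.89) rose most among genes that reached 5 CPM, along with the thyroglobulin gene TG. CSPG4 (log2 -6.30), IL7R (-5.96), IL2RA (-5.25), CLEC12A (-5.08), INHBA (-4.97) and DDN (-4.96) fell most there, per the authors' deposited table. With 35 nM, EFR3B (log2 7.28), EGR3 (7.13), EGR2 (6.51), DHRS2 (5.65) and AP3B2 (5.51) were among those that rose most at that level in the authors' deposited table. CCR2 fell from 2711 to 26.4 normalized counts (log2 -6.68) with 35 nM in the authors' deposited table, ahead, at that level, of CSPG4 (-6.67), IL7R (-6.61), CLEC12A (-6.60), IGLL1 (-6.29) and IL2RA (-5.97). MYC had a log2 of -0.98 with 1 nM and -0.98 with 35 nM in the authors' deposited tables, BCL2 of -0.87 and -1.35, HEXIM1 of 0.83 and 1.33, and CDKN1A of 1.78 and 2.15. PLK1 had a log2 of 0.89 and 0.78, and CCNB1 of 0.97 and 1.08, in the authors' deposited tables. By the authors' test with 1 nM, 8158 of 13520 tested genes passed an adjusted p of 0.05, 4105 higher and 4053 lower, of which 989 and 1015 changed by at least 2-fold. With 35 nM, 8787 of 13544 tested genes passed an adjusted p of 0.05, 4404 higher and 4383 lower, of which 1304 and 1306 changed by at least 2-fold.

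Among genes of NF-kB signalling and inflammation at 24 h, 15 of 20 measured members rose, 1 fell and 4 did not pass, the same as adjusted over the list alone with 1 nM and volasertib (median log2 1.36, adjusted p = 7.2e-06). With 35 nM and volasertib, 18 of 21 measured members rose and 3 did not pass, the same as adjusted over the list alone (median log2 1.797, adjusted p = 1.3e-07). TNF went from 211 to 1222 normalized counts with 35 nM (log2 2.54) in the authors' deposited table, while IER3 had a log2 of 5.28 and RELB of 2.12. C3, taken from the comparison of the combinations with BI00894999, had a log2 of 3.95 with 1 nM and 4.28 with 35 nM in the authors' deposited tables. The list was not called with either drug alone (adjusted p = 0.34 with 1 nM, 0.2 with 35 nM and 0.24 with volasertib), and the difference between these comparisons was not tested. Members also rose there: 7 of 18 with 1 nM, 9 of 20 with 35 nM and 6 of 17 with volasertib, while 2, 4 and 1 fell. The largest rises of a member were log2 3.21, 4.05 and 2.04. IER3 was not among the 5 genes that most exceeded BI00894999 alone at either dose, so its rise is not particular to the combinations. Among G2/M genes, 32 of 42 measured members rose, 3 fell and 7 did not pass, the same as adjusted over the list alone with 1 nM (median log2 0.47, adjusted p = 2.7e-13). With 35 nM, 36 of 42 measured members rose, 1 fell and 5 did not pass, the same as adjusted over the list alone (median log2 0.55, adjusted p = 1.3e-12). CKAP2 stood at log2 1.62 and HMMR at 1.496 for 1 nM in the authors' deposited table. Among G1/S genes, 1 of 38 measured members rose, 36 fell and 1 did not pass, the same as adjusted over the list alone with 1 nM (median log2 -0.63, adjusted p = 8.5e-17). With 35 nM, 35 of 38 measured members fell and 3 did not pass, the same as adjusted over the list alone (median log2 -0.75, adjusted p = 7e-17). MCM5 stood at log2 -1.61 and UNG at -1.89 for 35 nM in the authors' deposited table. Among MYC targets, 1 of 51 measured members rose, 41 fell and 9 did not pass, against 1 higher and 43 lower adjusted over the list alone with 1 nM (median log2 -0.54, adjusted p = 4e-11). With 35 nM, 1 of 51 measured members rose, 46 fell and 4 did not pass, the same as adjusted over the list alone (median log2 -0.66, adjusted p = 2.3e-13). The immediate early list rose with 1 nM, where 17 of 23 measured members rose, 3 fell and 3 did not pass, the same as adjusted over the list alone (median log2 1.24, adjusted p = 5.4e-16). It also rose with 35 nM, where 20 of 23 measured members rose, 2 fell and 1 did not pass, the same as adjusted over the list alone (median log2 1.802, adjusted p = 1.4e-21). The histone list rose with 1 nM, where 9 of 15 measured members rose, 2 fell and 4 did not pass, against 10 higher and 2 lower adjusted over the list alone (median log2 1.42, adjusted p = 0.00089). It also rose with 35 nM, where 13 of 17 measured members rose, 1 fell and 3 did not pass, against 14 higher and 1 lower adjusted over the list alone (median log2 2.28, adjusted p = 1.5e-05). Among the p53 targets, 13 of 25 measured members rose, 6 fell and 6 did not pass, the same as adjusted over the list alone with 1 nM (median log2 0.20, adjusted p = 0.018, but adjusted p = 0.12 with a correlation of 0.05). With 35 nM, 15 of 25 measured members rose, 6 fell and 4 did not pass, the same as adjusted over the list alone (median log2 0.31, adjusted p = 0.0042, but adjusted p = 0.053 with a correlation of 0.05). BTG2 stood at log2 3.20 for 35 nM in the authors' deposited table. The myeloid list fell, where 6 of 25 measured members rose, 15 fell and 4 did not pass, the same as adjusted over the list alone with 1 nM (median log2 -0.75, adjusted p = 3.6e-05, but adjusted p = 0.055 on ranks of the log2 fold change). With 35 nM, 6 of 25 measured members rose, 15 fell and 4 did not pass, the same as adjusted over the list alone (median log2 -1.01, adjusted p = 3.6e-05). LYZ stood at log2 -4.12 for 35 nM in the authors' deposited table. The P-TEFb list was called with 35 nM (median log2 0.24, adjusted p = 0.043, but adjusted p = 0.16 with a correlation of 0.05). Across the comparisons, the median of each called list had the sign of its test. Among lists not called, the signs differed in at least 1 comparison for the BET markers, MLL fusion targets, MYC targets, G1/S, NF-kB, spindle checkpoint, BCL2 family, ATF4, interferon-induced and mitochondrially encoded genes.

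**Figure D2:**
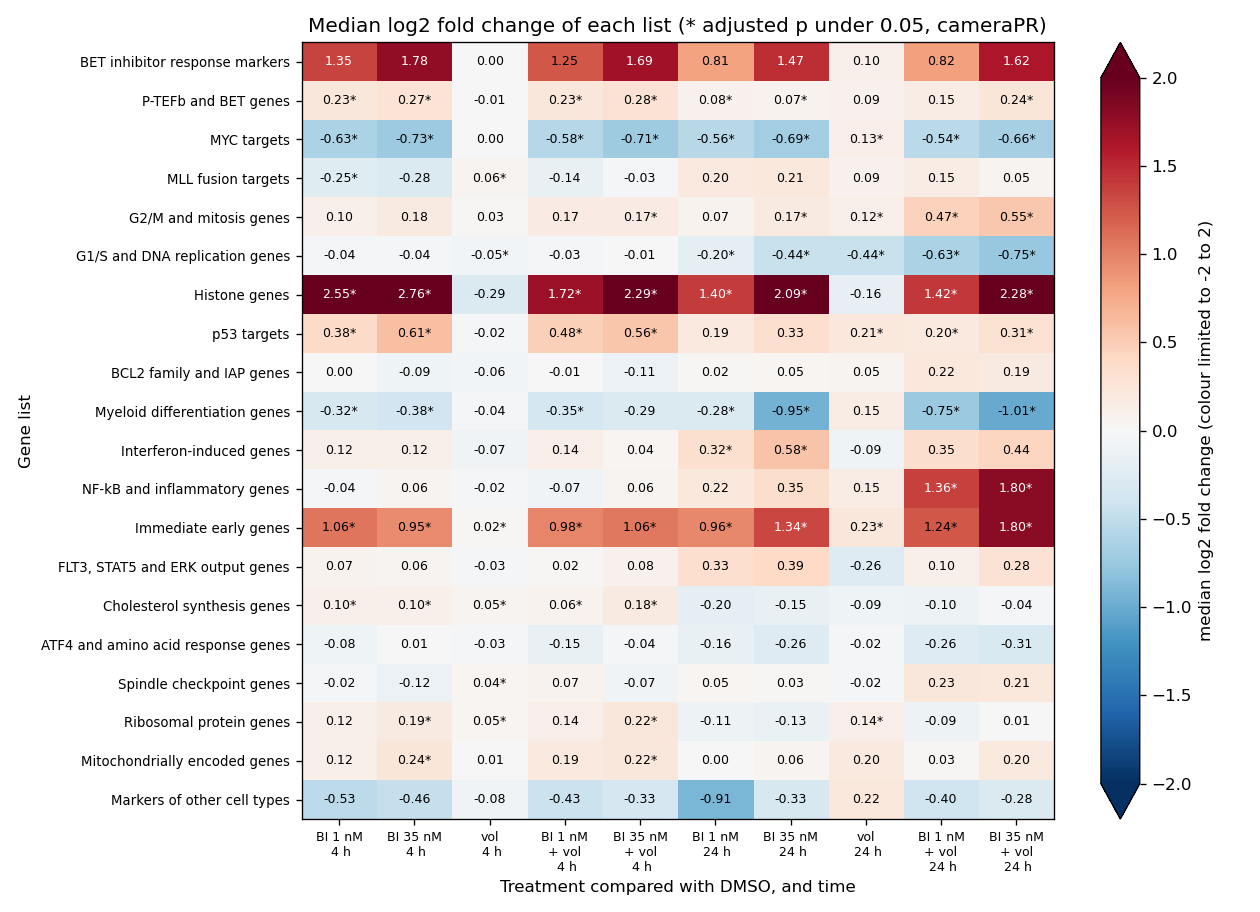
Each cell gives the median log2 fold change of a gene list (y axis) in a treatment compared with DMSO (x axis), coloured from -2 to 2, and a star marks an adjusted p under 0.05 in the list test. MYC targets ranged from -0.73 to -0.54 wherever BI00894999 was given, and the NF-kB list reached 1.36 and 1.797 in the combinations at 24 h.

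**Figure D3:**
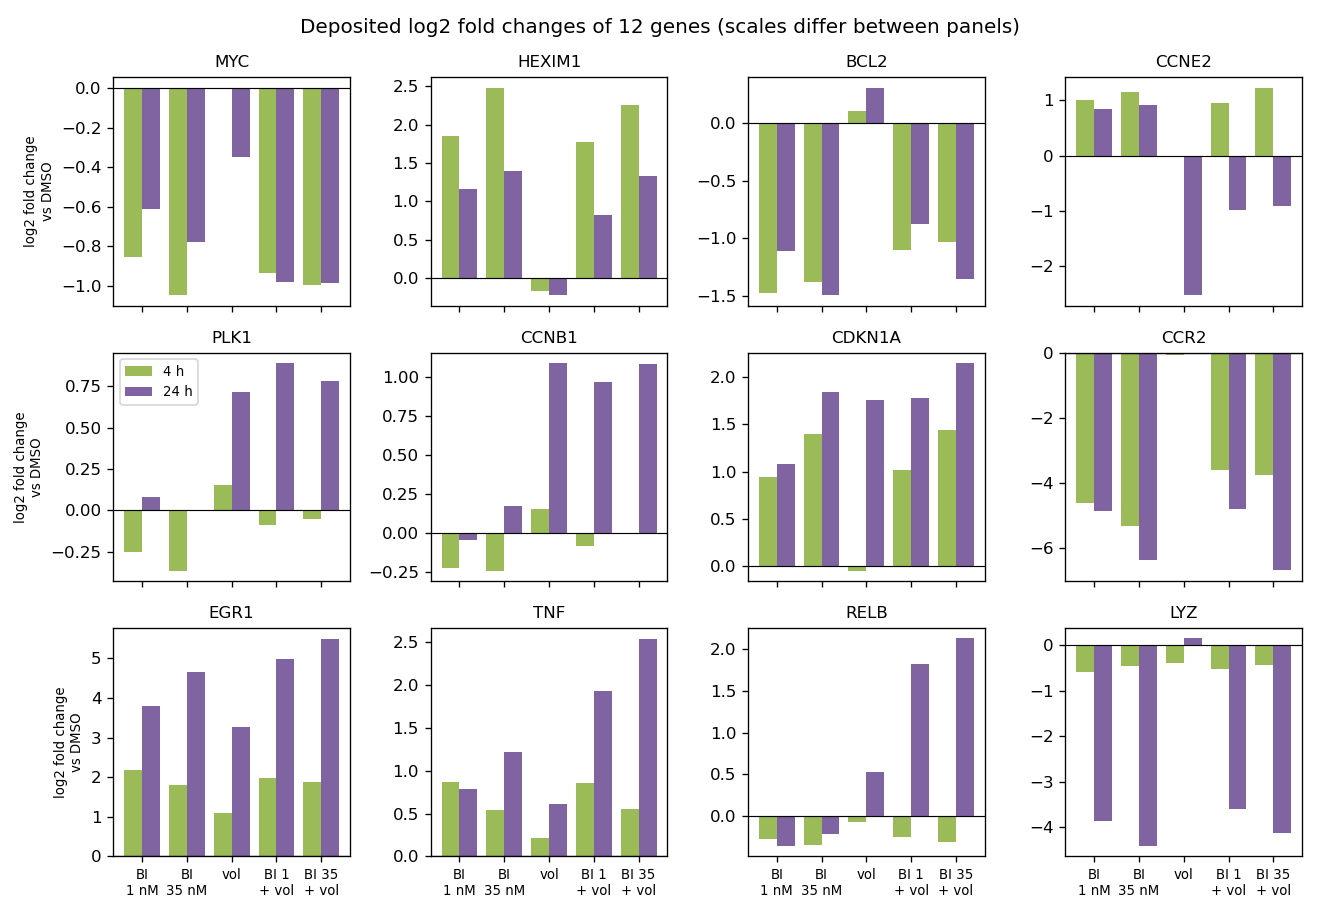
Bars give the deposited log2 fold change against DMSO (y axis, with its own scale in each panel) of 12 genes in 5 treatments (x axis) at 4 h (green) and 24 h (purple); the tables give no spread per group, so there are no error bars. For example, RELB stands at 0.53 with volasertib and 2.12 with 35 nM BI00894999 and volasertib at 24 h, per the authors' deposited table.

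How the dose of BI00894999 mattered was set out from values side by side. The tables had been normalized separately, so no test was made across them, here or for the comparisons that follow, and the differences printed are not shown to exceed the spread between libraries. DMSO means of the same libraries differed between tables, with an SD across genes of the log2 ratio of 0.0285 to 0.0591 at 4 h. At 24 h the SD was 0.0258 to 0.0707. Only genes with a DMSO mean of at least 50 in all 5 tables of a time entered, so genes of lower level are not covered. At 4 h the germ cell gene TEX14 had a log2 of 8.81 with 35 nM and 7.38 with 1 nM in the authors' deposited tables, BAIAP3 of 6.11 and 5.08, and HEXIM1 of 2.48 and 1.85. TEX14 did not reach 5 CPM with 1 nM, so its DMSO mean held few reads and the size of both of its values is uncertain. KANK1 stood at -4.80 and -3.48 and the retinoic acid receptor gene RARG at -3.46 and -2.24 in the authors' deposited tables. For histone genes at 4 h the median difference, 35 nM minus 1 nM, was 0.405 with 15 members above 0 and 2 below. At 24 h FOSB had a log2 of 3.18 with 35 nM and 1.37 with 1 nM in the authors' deposited tables, the membrane protein gene MS4A6A of -5.29 and -2.99, and CD180, a receptor of lymphoid and myeloid cells, of -3.42 and -1.51. The median difference at 24 h was -0.25 for G1/S genes (34 of 38 members below 0), 0.881 for histone genes (14 of 15 above 0) and -0.247 for myeloid genes (18 of 25 below 0). These medians lay outside the central 95% of 10000 random lists matched on level, which describes the tables and is no test. Of 340 such medians over all lists and contrasts 138 lay outside that range, where 17 would for lists of genes drawn at random. Members of a list may move together and the contrasts share libraries, so the number due to chance is not known.

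Volasertib on top of BI00894999 at 4 h was set beside BI00894999 alone. Among the genes at the upper extreme of the difference, the cytokine receptor gene IL15RA had a log2 of -2.003 against -3.67 with 1 nM alone, and NAV3 of -2.60 against -4.06, in the authors' deposited tables. With 35 nM, F2RL3 had -3.65 against -5.41, CCR2 -3.75 against -5.31 and KANK1 -3.28 against -4.80 in the authors' deposited tables. The treated means of F2RL3 hold few reads. HIST1H2AG had 1.65 against 2.64 with 1 nM, and PAN3-AS1 -0.51 against 0.24 with 35 nM, in the authors' deposited tables. MYC had -0.93 against -0.85 with 1 nM and -0.997 against -1.05 with 35 nM, per the authors' deposited tables. The median difference of the histone list was -0.36 with 1 nM (15 of 17 members below 0) and -0.173 with 35 nM (14 of 18 below 0). Set beside volasertib alone at 4 h, JUP had 4.48 with 1 nM and volasertib against -0.43, and HSH2D -4.63 with 35 nM and volasertib against -0.01, in the authors' deposited tables.

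At 24 h the combinations were likewise set beside BI00894999 alone. IL4I1, an amino acid oxidase gene of immune cells, had a log2 of 2.95 with both drugs against -1.03 with 35 nM alone in the authors' deposited tables. The chemokine gene IL8 had 2.85 against -0.33, EGR2 6.51 against 3.16, RELB 2.12 against -0.21 and C3 4.28 against 1.07, per the authors' deposited tables. With 1 nM, FOSB had 4.60 with both drugs against 1.37 in the authors' deposited tables. With 35 nM, CCNE2 had -0.92 against 0.91, and DDN -5.37 against -3.40, in the authors' deposited tables. PLK1 had 0.78 with 35 nM and volasertib against 0.00 with 35 nM alone, and CCNB1 1.08 against 0.17, per the authors' deposited tables. The median difference of the NF-kB list was 0.829 with 1 nM (17 of 18 members above 0) and 1.169 with 35 nM (18 of 20 above 0), and that of the G2/M list 0.418 (38 of 42 above 0) and 0.362 (39 of 42 above 0). The G1/S list had median differences of -0.456 with 1 nM (37 of 38 members below 0) and -0.32 with 35 nM (35 of 38 below 0). Relative to volasertib alone, with 35 nM and volasertib IER3 had 5.28 against 0.66, FGFR3 4.52 against 0.16 and FCER1A, a subunit gene of the IgE receptor, -6.75 against 1.43 in the authors' deposited tables. With 1 nM and volasertib FCER1A had -3.43 in the authors' deposited table. FCER1A is not among the genes listed at 5 CPM with 35 nM and volasertib, so its value there rests on few reads.

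The title of the series concerns synergy of the drugs, so the combination was also set against the sum of the log2 fold changes of the single agents. The same DMSO libraries enter all 3 terms, and their chance values do not cancel. At 24 h C3 lay above the sum by 3.19 with 1 nM and 2.01 with 35 nM, and IL4I1 by 1.77 with 1 nM. FAM222A lay above it by 2.375 and 2.226, TEX22 by 1.74 with 1 nM and ADAT3 by 2.141 with 35 nM. FAM222A had a log2 of -2.134 with volasertib alone, but 1.335 and 1.554 in the combinations. The libraries with volasertib alone enter every sum. At 24 h 2 of these 3 have internal numbers outside the run of the others, so a batch may contribute to any difference from the sum. IGLL1 lay above the sum by 2.49 with 35 nM (log2 -6.285 with both drugs, -8.535 with 35 nM and -0.245 with volasertib). Its means with BI00894999 were of few normalized counts, so this excess rests on few reads. EGR1 differed from the sum by -2.09 with 1 nM and -2.44 with 35 nM, CDKN1A by -1.06 and -1.46, and FCER1A by -1.67 and -4.41. With 35 nM and volasertib the log2 of FCER1A (-6.747) would be lowest among genes listed at 5 CPM, yet it is not among them. Its difference with 35 nM therefore rests on few reads. MYC differed by -0.02 with 1 nM and 0.14 with 35 nM, and BCL2 by -0.07 and -0.16. The NF-kB list had a median excess over the sum of 0.48 with 1 nM and 0.656 with 35 nM, each with 14 of 17 members above 0. The G2/M list had a median excess of 0.307 with 1 nM (37 of 42 above 0) and 0.209 with 35 nM (35 of 42 above 0), and p53 targets one of -0.056 with 1 nM (16 of 25 below 0) and -0.182 with 35 nM (17 of 25 below 0). Other medians outside the range of random lists at 24 h were those of immediate early genes (0.299 with 1 nM and 0.214 with 35 nM), spindle checkpoint genes (0.164 and 0.218) and cholesterol synthesis genes (0.116 and 0.242), of myeloid genes with 1 nM (-0.22), and of G1/S genes (0.082) and FLT3, STAT5 and ERK outputs (0.241) with 35 nM. The p53 median with 1 nM lay inside it. At 4 h the medians outside the range with 35 nM were 0.06 for MYC targets (38 of 51 above 0), 0.071 for G1/S genes (29 of 38 above 0), 0.047 for G2/M genes, 0.081 for spindle checkpoint genes, 0.088 for myeloid genes, 0.09 for the BCL2 family, -0.156 for histone genes and, at the edge of the range, -0.033 for cholesterol synthesis genes. With 1 nM they were 0.041 for MYC targets and -0.088 for cholesterol synthesis genes. With 35 nM F2RL3 lay above the sum by 1.95 and EGR1 differed from it by -1.002. The treated means of F2RL3 hold few reads, so the size of its excess is uncertain.

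Effects at 24 h were set beside those at 4 h, each against its own DMSO libraries. With 35 nM BI00894999, IGLL1 had a log2 of -8.53 at 24 h and -0.38 at 4 h in the authors' deposited tables, CST7, an inhibitor of proteases, -6.28 and -0.56, RARG 0.06 and -3.46, and HEXIM1 1.40 and 2.48. With volasertib, NCF1, a subunit gene of the phagocyte oxidase, had 2.62 and -0.11, CCNE2 -2.53 and -0.01 and CDKN1A 1.76 and -0.05 in the authors' deposited tables. With 35 nM and volasertib, IL8 had 2.85 and -2.74, the haem oxygenase gene HMOX1 4.10 and -0.18, and TEX14 3.08 and 8.57 in the authors' deposited tables. The value of TEX14 at 4 h starts from few DMSO reads. The G1/S list had a median difference, 24 h minus 4 h, of -0.4 with 35 nM BI00894999 (35 of 38 members below 0), -0.384 with volasertib (37 of 38 below 0) and -0.793 with both (38 of 38 below 0). Of genes that rose at 4 h with 35 nM BI00894999, 2688 also rose at 24 h, where independent lists would share 1287.9, and 3032 fell at both times, where independent lists would share 1438.8. With 1 nM 2006 rose at both times (812.2 by chance) and 2280 fell (922.0 by chance). With volasertib 10 rose at both times (4.2 by chance) and 16 fell (4.0 by chance). With 35 nM and volasertib 2702 rose (1263.7 by chance) and 2789 fell (1322.5 by chance), and with 1 nM and volasertib 2163 rose (990.2 by chance) and 2291 fell (1064.3 by chance).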

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

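Leaving out tied genes, the correlation of 0.05 and the tests on ranks were chosen after the data were seen; the other settings were planned. With an added log2 fold change of at least 1, counts of genes past the threshold were 1658 with 1 nM, 2365 with 35 nM, 3 with volasertib, 1561 with 1 nM and volasertib and 2076 with 35 nM and volasertib at 4 h, and 1401, 2471, 506, 2004 and 2610 in that order at 24 h. The criterion is stricter by construction. At an adjusted p under 0.01 the count for volasertib at 4 h was 21, and the other 9 counts stayed within 1.5 times. The stricter filter on level and leaving out tied genes kept all 10 counts within 1.5 times. Of 200 list tests, 27 lost their call with a correlation of 0.05, 20 with ranks of z and 34 with ranks of the log2 fold change, while 5 and 3 gained one on these ranks. None of the 77 called lists turned direction under these settings. Of the lists not called, 15 pointed the other way on ranks of z and 18 on ranks of the log2 fold change. Among the named genes 30 calls were lost at 0.01 and 335 with the log2 criterion. No paired analysis was possible because the tables give group means and no values per library. For the same reason DESeq2, other normalization factors, a fit without the 3 libraries of odd internal number at 24 h, each library left out, another pseudocount, a fit on the groups of 1 comparison, an estimated correlation and other splits of the samples were not run; no filter is the deposited state. Depth per library is unknown, so no limit of detection is given.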

Other observations

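Among the tests below, rounding of tied values, the split of genes with 1 exon by level, the shift of whole tables and the noise of members with few reads were chosen after the result was seen; the others were set beforehand.

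Interferon-induced genes rose as a list after 24 h of BI00894999. With 1 nM, 12 of 26 measured members rose, 3 fell and 11 did not pass, the same as adjusted over the list alone (median log2 0.32, adjusted p = 0.022, but adjusted p = 0.14 with a correlation of 0.05), and with 35 nM, 14 of 27 measured members rose, 5 fell and 8 did not pass, the same as adjusted over the list alone (median log2 0.58, adjusted p = 0.048, but adjusted p = 0.21 with a correlation of 0.05). IRF7, the regulator of interferon genes, had a log2 of 2.18, IFI6 of 2.51, XAF1 of -1.90 and the antiviral synthetase gene OAS2 of -0.79 with 35 nM at 24 h in the authors' deposited table. With volasertib alone at 24 h the list was not called (adjusted p = 0.94), nor was it in the combinations (adjusted p = 0.13 and 0.091). The list of cholesterol synthesis genes was called upward in all 5 comparisons at 4 h. These share the same DMSO libraries, so the 5 calls are not independent. With volasertib alone 24 of 24 measured members did not pass, against 1 higher adjusted over the list alone (median log2 0.05, adjusted p = 0.001, and 0.023 with a correlation of 0.05, but adjusted p = 0.055 on ranks of the log2 fold change). With 1 nM, 10 of 24 measured members rose, 4 fell and 10 did not pass, against 11 higher and 4 lower adjusted over the list alone (median log2 0.10, adjusted p = 0.015, but adjusted p = 0.11 with a correlation of 0.05). With 35 nM, 10 rose, 3 fell and 11 did not pass, the same as adjusted over the list alone (median log2 0.10, adjusted p = 0.012, but adjusted p = 0.098 with a correlation of 0.05). With 1 nM and volasertib, 10 rose, 4 fell and 10 did not pass, the same as adjusted over the list alone (median log2 0.06, adjusted p = 0.017, but adjusted p = 0.11 with a correlation of 0.05). With 35 nM and volasertib, 11 rose, 4 fell and 9 did not pass, against 12 higher and 4 lower adjusted over the list alone (median log2 0.18, adjusted p = 0.0053, but adjusted p = 0.058 with a correlation of 0.05). The sterol reductase gene TM7SF2 had a log2 of 2.52 and the oxidase gene MSMO1 of -1.09 with 35 nM at 4 h in the authors' deposited table. At 24 h no call was made for this list with 1 nM (adjusted p = 0.24), 35 nM (0.18), volasertib (0.12), 1 nM and volasertib (0.48) or 35 nM and volasertib (0.85).

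Genes of the ATF4 and amino acid response moved both ways and were not called: with 35 nM at 24 h, 6 of 25 measured members rose, 15 fell and 4 did not pass, the same as adjusted over the list alone (adjusted p = 0.19). SLC7A5, an amino acid transporter gene, had a log2 of -1.31, XPOT, an exporter of tRNA, of -0.79 and SESN2 of 1.25 there in the authors' deposited table. Among outputs of FLT3, STAT5 and ERK, 10 of 21 measured members rose, 7 fell and 4 did not pass, the same as adjusted over the list alone with 35 nM at 24 h (adjusted p = 0.36). The phosphatase gene DUSP6 had a log2 of 1.64, the transcription factor gene ETV5 of 1.24, IL2RA of -6.41 and the cyclin gene CCND2 of -1.06 in the authors' deposited table.

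Several of the most abundant genes share exactly 1 value. In the table for 35 nM at 4 h, 10 genes share the highest DMSO mean of 91106.7, and 8 of them (ACTB, FTL, SRGN, RPL36, RPL4, MT-ND2, MT-CO1 and MT-ND4, singled out after their values were seen) also share the treated mean of 107846 and a log2 fold change of 0.243. Rounding is excluded, since different DMSO means above 10000 stand as close as 0.96 or closer in each of the 10 tables. A candidate explanation is a quantile step within bins of GC content or length, which would put tied pairs in the same of 10 bins less often: the share of 1457 pairs was 7.69% for GC content, toward the low end of the shuffled range (7.28 to 13.93%, percentile 5.8), and 12.63% for length, above the shuffled median of 10.16 (7.28 to 14%, percentile 90.9) and so against the predicted direction. The bound set beforehand took a share inside the shuffled range as evidence against the step, which was wrong because a range this wide also holds the shares that a partial effect would give, so a partial step stays open, with no value in favour of one by length, and no biological explanation was tested.

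Genes with 1 exon stood lower than others with volasertib at 24 h. Their median log2 fold change lay -0.301 from that of genes with several exons (-0.29 for coding genes), against -0.037 with volasertib at 4 h, 0.019 and 0.068 with 1 nM and 35 nM at 24 h, and -0.104 and -0.051 in the combinations at 24 h; at 4 h it was 0.137 and 0.213 with BI00894999 and 0.127 and 0.161 in the combinations. Less carry-over of unspliced or genomic sequence in those libraries may account for it and would lower genes of low level more, but the difference of -0.276 below and -0.181 above the median level differed by -0.095 (95% bootstrap interval across genes, which are not replicates, -0.272 to 0.077), which decides nothing. The internal numbers of 2 of the 3 volasertib libraries at 24 h stand outside the run of the others, so for volasertib alone a batch and the drug cannot be told apart from group means. The libraries with 1 nM and volasertib have no such number, and genes with 1 exon also lay lower there (-0.104, against 0.019 with 1 nM alone). Whether that smaller difference exceeds the spread between libraries is not known. An effect of the drug on such genes was not tested and stays open.

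The NF-kB list rose in both combinations at 24 h, and its median member stood above the sum of the single agents. A shift that moves all genes of a table alike, through its separate normalization, is excluded as the whole cause. The list's median excess of 0.48 with 1 nM and 0.656 with 35 nM lay above the central 95% of random lists matched on level, by at least 0.243. A normalization that acts by GC content or length is not covered and stays open, since the random lists were matched on level only and drawn gene by gene. Among the 12 of 17 members with means of at least 50, the median excess was 0.681 with 35 nM (10 above the sum). With 1 nM the 12 had 0.451 (11 above), short of the bound of 0.5 that the value with 35 nM passed. That bound was set after the result was seen and takes no account of spread, and the means pool DMSO and treated libraries. Noise of members with few reads thus stays open at both doses, though the excess with 35 nM was not confined to such members. A joint action of the drugs on these genes is a hypothesis that stays open, as does a batch: 2 of the 3 libraries with volasertib alone, which enter both sums, and 1 of the 3 with 35 nM and volasertib have internal numbers outside the run, while those with 1 nM and volasertib do not. Chance values of the DMSO libraries, which do not cancel in the sum, may also contribute and were not tested, and the excess was found and examined on the same data.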
